A study of Mus musculus with 3 samples.

How the data were processed

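Single-cell RNA was captured with gene-specific probes from fixed, viable CD45-positive cells of mouse liver at postnatal day 0, in 3 libraries: Pex2 wild type, heterozygous and null, with 1 library per genotype. The number of animals behind each library is not given in the sources used here. Per the labels' protocols, livers were pressed through a strainer, spun slowly against hepatocytes, treated with a red cell lysis buffer, and sorted for CD45 and viability. Per the submitters' processing notes and the file headers, the authors made the deposited counts with Cell Ranger 7.0.0 against mm10. Each deposited matrix holds whole-number UMI counts of 19059 genes by barcode, not normalised. Settings of the aligner, the probe set version and any filter on barcodes beyond the tool's own are not given in the sources used here. Fold differences here compare only the probed part of each transcript. Genes with near-identical copies, such as the glutathione transferases, chitinase-like proteins, C-type lectins and immunoglobulin segments, may share probes, and their values are uncertain.

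Annotation by the submitters was not used here, and classes were rebuilt. A minimum of 200 detected genes removed 0 barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5 at its automatic threshold, which marked 273, 186 and 298 barcodes (2.84%, 2.33% and 3.61%) and left 9327, 7814 and 7947 cells. Counts were log-normalised, and 2000 variable genes, without sex-linked genes and Pex2, gave 40 principal components, 20 neighbours and Leiden clusters at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). The libraries were clustered together without batch correction. A cluster of at least 60 cells was split again at resolution 0.5 when another class had 3 or more markers among its top 30 genes, which gave 48 clusters. A cluster was named from marker lists fixed in advance when at least 2 markers of a class were among its top 10 genes by fold and at least 3 were detected. Detection required a 2-fold difference, with 10 CPM added, and a UMI in 20% of the cells. The reference was the clusters whose marker profile correlated below 0.3. Classes are therefore called like the named cell type, and other names could come from another annotation.

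UMIs were summed per library over all barcodes and per library and class over cells kept, for 10 classes or families with at least 50 cells in each library. Plasmacytoid dendritic-like cells were added with a minimum of 20. Values are CPM of the class or library total, with exact Poisson intervals. Ratios carry exact conditional binomial intervals, and log2 ratios have 0.5 counts added to each sum. Shares of cells carry exact Clopper-Pearson intervals at a level of 95%. All intervals cover counting error only. With 1 library per genotype there was no test, and labelled Het against labelled WT served as the only gauge of differences between libraries. For shares of cells with a UMI, each cell was thinned to 3000 UMIs, which left out 766, 290 and 323 shallower cells and kept 8561, 7524 and 7624.

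Genes were named by size. A named gene had a mean of at least 50 CPM and at least 30 UMIs, its KO value lay outside both other libraries on the same side, and both intervals excluded 1. Genes were ranked by the smaller of the absolute log2 ratios, and the first 10 in each direction over all cells and 5 in each class were taken, with Pex2, Y-linked genes and leading members of gene lists besides. In monocyte-like cells 1 gene that met this rule is not reported here. The 32 lists used members with a mean of at least 10 CPM. Each median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. The gene position of Pex2 and of genes near it came from the GRCm38 annotation.

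The naming rule was tested on simulated data with 200 changed genes. Counts were drawn from a profile shared by all libraries, with counting error only. The rates below therefore leave out any other difference between libraries or animals. Over all cells it named 50 of 50 genes raised 2-fold and 40 of 50 lowered 2-fold, and it named 24 of 3778 unchanged genes (0.635%). The intervals held the true ratio for 94.9% of 3978 genes. In macrophage-like cells intervals held it for 96.1% of 4365 genes, and 10 of 4164 unchanged genes were named (0.240%). There it named 50 of 50 genes raised and 43 of 50 lowered 2-fold, but only 24 and 21 of 50 raised or lowered about 1.3-fold.

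Depth differed between the libraries, with medians of 2473, 3713 and 3944 genes per cell. The 10 highest genes took 23.3%, 22.7% and 26.3% of UMIs, haemoglobin genes 0.0112%, 0.0309% and 0.00896%, mitochondrial genes 0.142%, 0.182% and 0.311%, and hepatocyte genes 0.000568%, 0.000739% and 0.00157%. TMM factors came from edgeR 4.0.16 and median-of-ratios size factors from DESeq2 1.42.0 in R 4.3.3, as alternative scalings only. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

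The markers, gene lists, comparisons, naming rule for genes and a first set of alternatives were chosen before the data were examined. That set covered other Leiden resolutions, doublets kept, clustering after thinning, cell-cycle genes left out, each library clustered alone, classes from a marker score per cell, erythroid-like and unnamed cells left out, other scalings, 5 counts added, other CPM minimums and classes weighted equally. Classes weighted equally means that each class had the same weight in every library, its mean share over the libraries. That weight was applied to the class's mean UMIs per cell, so large classes and deep cells still counted most. With doublets kept, cells were clustered and named anew, so a class could hold other cells. Later choices, made with the clusters and class shares in view, were the rules that name and split clusters, which were revised several times, the splits of macrophage-like and plasmacytoid dendritic-like cells by sub-cluster, the share of MHC class II UMIs by class, neutrophil and hepatocyte genes in other classes, and a glucocorticoid gene list. Alternatives added then were libraries centred before clustering, no sub-clustering, an earlier sub-clustering rule, smaller classes and Pex2 after thinning.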

Results

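Gene expression was measured by probe capture in single fixed cells from the livers of newborn mice (postnatal day 0). The mice carried normal, heterozygous or null alleles of Pex2, which encodes a membrane protein that peroxisomes need in order to import their enzymes. Loss of this protein models severe Zellweger disease. Viable cells bearing CD45, the common leukocyte surface protein, were sorted after a slow spin against hepatocytes and lysis of red cells. There was 1 library per genotype, so every difference below lies between 3 libraries, has no replicate check and was not tested. The library labelled WT held 9600 barcodes and 96629431 UMIs (unique molecular identifiers, counts of captured molecules), with a median of 8218.5 UMIs per cell. The library labelled Het held 8000 barcodes and 144589956 UMIs, with a median of 15558.5, and the KO library held 8245 barcodes and 186295183 UMIs, with a median of 19348. Expression is given in CPM (a gene's UMI count scaled to a library or class total of 1000000 UMIs) in the order labelled WT, labelled Het and KO, and intervals cover counting error only.

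Pex2 checks the labels. Pex2 (ENSMUSG00000040374, chromosome 3, 5560188 to 5576239, minus strand, GRCm38) was nearly absent from the KO library, with 2 UMIs, or 0.0107 CPM (95% Poisson interval 0.00130 to 0.0388). The library labelled WT held 2283 Pex2 UMIs, or 23.6 CPM (22.7 to 24.6), and the library labelled Het held 7704, or 53.3 CPM (52.1 to 54.5). Pex2 was therefore 2.25-fold higher in the library labelled Het than in that labelled WT (2.15 to 2.36), against the order that the labels give. A Pex2 UMI was found in 19.0% of cells of the library labelled WT (exact binomial interval 18.2 to 19.8), in 47.0% of the library labelled Het (45.9 to 48.1) and in 0.0243% of the KO library. The same order held in macrophage-like cells (14, 50 and 0 UMIs), B-lineage cells (251, 687 and 0) and monocyte-like cells (342, 1008 and 0). Whether the probe lies inside the deleted part of Pex2 is not given in the sources used here, although its signal was nearly lost in KO, as that label predicts. The 2 control libraries are called by their labels throughout, because Pex2 goes against them.

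**Figure D1:**
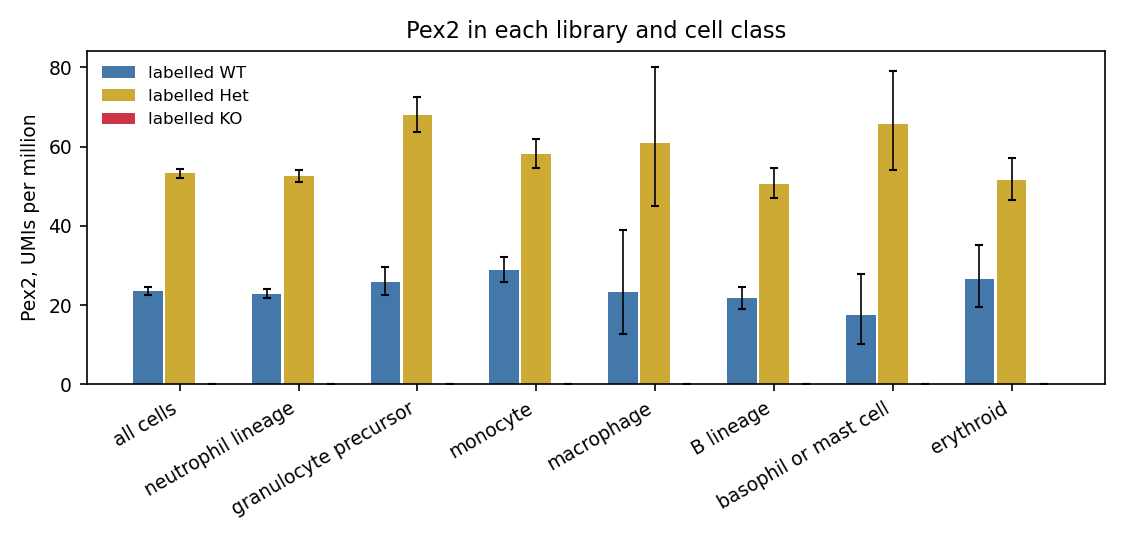
Pex2 CPM on the vertical axis for each cell class, with 1 bar per library and exact Poisson intervals. The KO bars lie at about 0 in every class, and over all cells the library labelled Het (53.3 CPM) lies above that labelled WT (23.6 CPM).

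The libraries also differed in sex-linked expression. Ddx3y, a Y-linked RNA helicase, had 7956 UMIs in the library labelled WT, 2 in that labelled Het and 3 in KO. Eif2s3y, a Y-linked translation factor, had 5322, 2 and 7 UMIs. Among cells with at least 20000 UMIs, 727 of 757 (96.0%) in the library labelled WT, 0 of 2754 in that labelled Het and 4 of 3761 (0.106%) in KO held a UMI of a Y-linked gene. KO against labelled WT thus also set a library without Y-linked expression against one with it, whereas KO against labelled Het did not.

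The first comparison asked which immune cell classes formed the newborn liver's CD45-positive pool in each library. Neutrophil-lineage-like cells made up most of every library, at 64.7%, 64.1% and 67.3% of cells. Monocyte-like and macrophage-like cells took a larger share in KO than in either other library, while B-lineage-like, stem and progenitor-like and dendritic-cell-like cells took a smaller one. Monocyte-like cells were 8.06% of the library labelled WT (95% Clopper-Pearson interval 7.52 to 8.63), 9.19% of that labelled Het (8.56 to 9.85) and 14.9% of KO (14.2 to 15.8). The KO share was 1.85 times that in the library labelled WT (1.69 to 2.03) and 1.63 times that labelled Het (1.48 to 1.79). B-lineage-like cells were 20.5%, 16.9% and 11.7%, and the KO share was 0.570 times the labelled WT share (0.526 to 0.616) and 0.693 times the labelled Het share (0.636 to 0.754).

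Stem and multipotent progenitor-like cells, which are early blood-forming cells, numbered 97, 106 and 19. Their KO share was 0.230 times the labelled WT share (0.133 to 0.379) and 0.176 times the labelled Het share (0.102 to 0.289). Conventional dendritic cell type 1-like cells, specialists in antigen presentation, numbered 25, 40 and 8, with KO share ratios of 0.376 (0.146 to 0.859) and 0.197 (0.0795 to 0.426). These depended on the clusters formed: without sub-clustering they were 0.575 and 0.415, and the second was 0.324 with cell-cycle genes left out and 0.379 with a marker score per cell. Plasmacytoid dendritic-like cells, the main producers of type I interferon, numbered 83, 40 and 23, with KO share ratios of 0.325 against labelled WT (0.196 to 0.521) and 0.565 against labelled Het (0.323 to 0.967). Macrophage-like cells were 0.804%, 0.985% and 1.46%, a KO share 1.81 times that labelled WT (1.35 to 2.46) and 1.48 times that labelled Het.

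Natural killer and type 1 innate lymphoid-like cells were 0.172%, 0.601% and 0.730%, so the library labelled WT was the lowest. Erythroid-like cells were 1.31%, 3.28% and 1.71%, so the library labelled Het was the highest. Basophil or mast-like cells (0.761%, 0.909% and 0.717%) and eosinophil-like cells (0.193%, 0.282% and 0.176%) gave KO ratios whose intervals included 1, although the basophil or mast-like ratio of KO over labelled WT was 1.46 when each library was clustered alone. The neutrophil-lineage ratio of KO over labelled WT, 1.04 (1.00 to 1.08), turned to 0.996 when cells were clustered after thinning, while that over labelled Het, 1.05 (1.01 to 1.09), did not turn. Labelled Het over labelled WT gauged how far libraries differed without loss of both alleles, and it was 1.14 for monocyte-like (1.03 to 1.26), 0.822 for B-lineage-like (0.766 to 0.882) and 3.51 for natural killer-like cells (1.95 to 6.63). It was 1.91 for dendritic cell type 1-like (1.13 to 3.29) and 0.575 for plasmacytoid dendritic-like cells (0.384 to 0.849), the latter nearly as large a difference as KO over labelled Het gave. Sorting, red cell lysis and the slow spin all act on these shares.

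**Figure D2:**
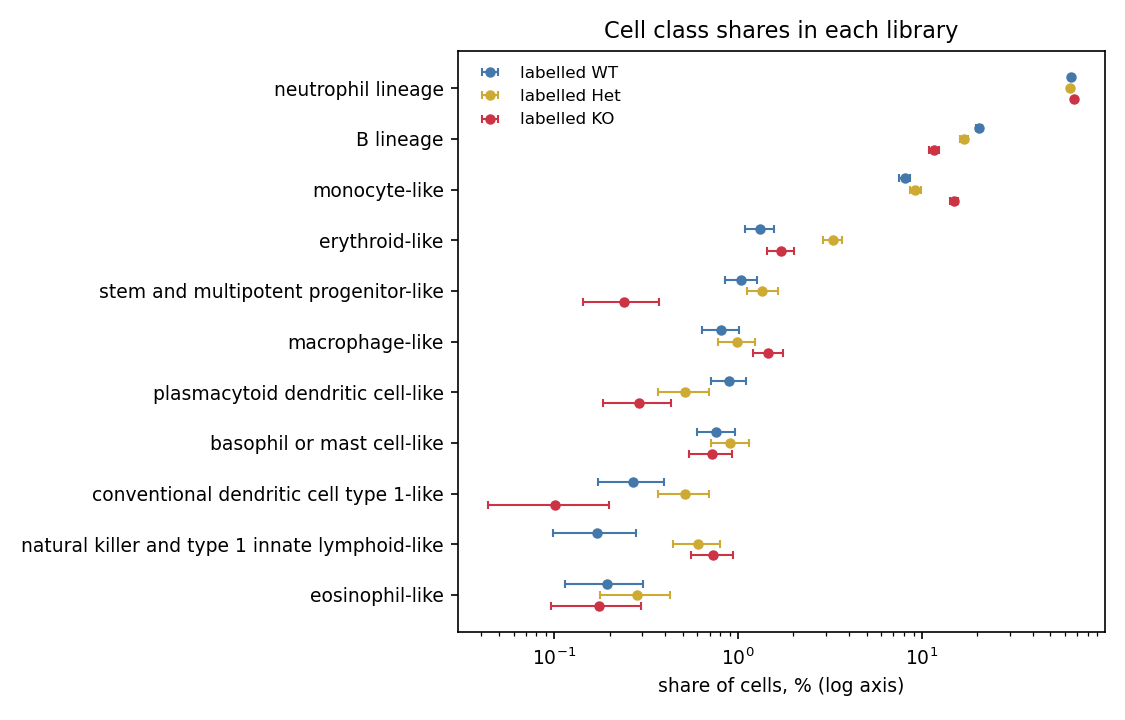
Share of cells in percent on a log axis for 11 cell classes, with 1 point per library and exact Clopper-Pearson intervals. Monocyte-like cells reach 14.9% in KO against 8.06% and 9.19%, and stem and progenitor-like cells lie at 0.239% against 1.04% and 1.36%.

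Most clusters of the larger classes held cells mainly of 1 library or of the 2 control libraries. Neutrophil clusters 4 and 9 held 1440 and 912 KO cells and 0 labelled WT cells, while clusters 2 and 3 held 1970 and 1452 labelled WT cells and 2 KO cells each. Most monocyte-like KO cells lay in clusters 17 (703 cells) and 20 (485), which also held 34 and 18 labelled Het cells and 2 and 5 labelled WT cells. Most monocyte-like control cells lay in clusters 8 (524 labelled WT, 419 labelled Het and 0 KO) and 21 (221, 247 and 0). A cluster made mostly of 1 library may be that library and not a cell type, so values for stages within the neutrophil and B lineages are uncertain. Unnamed clusters held 1.27%, 1.43% and 0.654% of cells.

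The second comparison asked which genes differed over all sorted cells, where composition and expression act together. Pla2g7 led the genes higher in KO, and Gstp3 and Igll1 led those lower in KO. Pla2g7, a secreted enzyme that breaks down platelet-activating factor, was at 63.9, 93.9 and 260 CPM, 4.07-fold above the library labelled WT (3.97 to 4.18) and 2.77-fold above that labelled Het (2.72 to 2.82). Chil3, a chitinase-like protein of neutrophils and macrophages, was at 3921, 6551 and 16013 CPM. Il1r2, the decoy receptor for interleukin 1, was at 48.9, 122 and 291 CPM, and Fn1, which encodes fibronectin, at 446, 489 and 1272 CPM. Tgfbi, a matrix protein induced by transforming growth factor beta, was at 75.7, 108 and 275 CPM, and Smpdl3a, a nucleotide phosphodiesterase made by macrophages, at 53.5, 84.8 and 215 CPM. Ap1s2, a coat protein of vesicles, was at 65.4, 63.4 and 171 CPM, and Trp53inp1, a stress protein under p53, at 94.1, 86.8 and 229 CPM. With each class given the same weight in every library, the log2 ratios of Fn1 shrank from 1.51 to 0.71 against labelled WT. Against labelled Het they shrank from 1.38 to 0.68.

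Gstp3 (ENSMUSG00000058216), a glutathione transferase of the pi family, was at 113, 96.7 and 3.44 CPM, or 32.9-fold below labelled WT and 28.1-fold below labelled Het. Igll1, part of the surrogate light chain of the pre-B-cell receptor, was at 108, 78.4 and 6.65 CPM. Cbfa2t3, a corepressor in blood progenitors, was at 86.0, 59.2 and 12.9 CPM, and Ccnd2, a cyclin of the G1 phase, at 77.6, 87.2 and 19.3 CPM. Sox4, a transcription factor of early lymphoid cells, was at 124, 84.3 and 24.3 CPM, and Prss34, a basophil protease, at 92.0, 82.1 and 21.6 CPM. Mzb1 and Pou2af1, which support antibody assembly and B-cell transcription, gave log2 ratios of KO over labelled Het of -1.74 and -1.68. Ptprcap, a partner of CD45, gave -1.73, and Adgrg1, an adhesion receptor of stem and cytotoxic cells, gave -1.89. Weighting classes equally shrank these to -0.89 for Mzb1, -1.12 for Ptprcap and -0.38 for Adgrg1, shrank the KO over labelled WT value of Igll1 from -4.03 to -1.15 and the KO over labelled Het value of Sox4 from -1.80 to -1.03 and of Ccnd2 from -2.18 to -1.40, and gave -1.17 for Pou2af1 against labelled WT.

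Lists of genes fixed before the data were examined gave a broader view, each described by the percentile of its median among 10000 random lists matched on expression. Mitochondrially encoded genes were the highest list in KO over all cells, with median log2 ratios of 1.11 against labelled WT and 0.72 against labelled Het, both at percentile 100. Within this list mt-Nd1, a subunit of respiratory complex I, was at 56.9, 106 and 275 CPM and mt-Atp6, a subunit of ATP synthase, at 147, 195 and 493, while mt-Nd6 went the other way at 143, 68.7 and 37.0 CPM. Labelled Het over labelled WT was also high for this list, at 0.53 (percentile 100). Lysosome and phagocytosis genes were modestly higher, at 0.29 and 0.25 (percentiles 99.8 and 100), led by Lgals3, a galectin of phagocytes (928, 984 and 1686 CPM), and the lysosomal membrane gene Lamp2 (155, 187 and 304).

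Stress-response and glycolytic genes were lower in KO over all cells. Genes of the unfolded protein and integrated stress response had medians of -0.39 (percentile 1.74) and -0.64 (percentile 0), with 20 of 25 members below both other libraries. Atf4, the transcription factor at the centre of this response, was at 67.8, 62.0 and 28.8 CPM, and the serine pathway enzymes Shmt2 and Psat1 were at 131, 162 and 60.4 CPM and at 39.9, 59.8 and 21.7 CPM. Genes of glycolysis and hypoxia had medians of -0.51 (percentile 0.25) and -0.46 (percentile 0.02), with Ldha, which makes lactate, at 552, 545 and 298 CPM. Under TMM scaling the glycolysis median against labelled Het turned to 0.01 while the median of all genes moved to 0.18, so the list stayed below the other genes. The median over all genes was -0.13 against labelled WT and -0.16 against labelled Het, and TMM scaling lifted these to 0.15 and 0.18 (to 0.19 and 0.21 in the neutrophil lineage), so directions of small medians hold only relative to the other genes.

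Blood transcription factors and pre-B genes were also lower in KO over all cells. Haematopoietic transcription factors had medians of -0.68 and -0.53 (both percentile 0), with Gata2, which maintains stem cells and mast cells, at 50.5, 41.4 and 10.3 CPM and Ebf1, which commits cells to the B lineage, at 98.5, 61.0 and 22.7. Pre-B receptor and recombination genes had medians of -1.32 and -1.07 (both percentile 0), with Pax5, which keeps B-cell identity, at 126, 70.7 and 31.0 CPM. The pre-B median against labelled WT was -0.51 with classes weighted equally. Haemoglobin and red cell membrane genes had medians of -0.79 (percentile 2.74) and -1.81 (percentile 0.02) over 4 members, and labelled Het lay above labelled WT by 1.15 (percentile 100). The median against labelled WT was -0.14 when members down to 1 CPM were taken, and that against labelled Het was -0.89 with classes weighted equally.

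Peroxisomal genes themselves moved little as groups. Peroxisome biogenesis genes had medians of -0.24 (percentile 42.4) and -0.16 (percentile 69.6) over 13 members, and peroxisomal enzymes and transporters had -0.00 (percentile 85.0) and 0.04 (percentile 98.7) over 23. Under TMM scaling the biogenesis medians turned to 0.04 and 0.18. Single members differed: Idh1, which makes NADPH in peroxisomes and cytosol, was higher in KO at 32.0, 33.4 and 65.8 CPM, as was Abcd2, a transporter of very long chain fatty acids (89.6, 84.7 and 147). Tysnd1, the protease that trims imported peroxisomal enzymes, was lower at 43.2, 35.1 and 19.7 CPM. Fatty acid oxidation and PPAR targets had medians of -0.09 (percentile 59.6) and -0.25 (percentile 20.9), the second turning to 0.10 under TMM scaling. Cholesterol biosynthesis genes had -0.54 (percentile 1.5) and -0.37 (percentile 13.6), with 18 of 23 members below both other libraries.

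**Figure D3:**
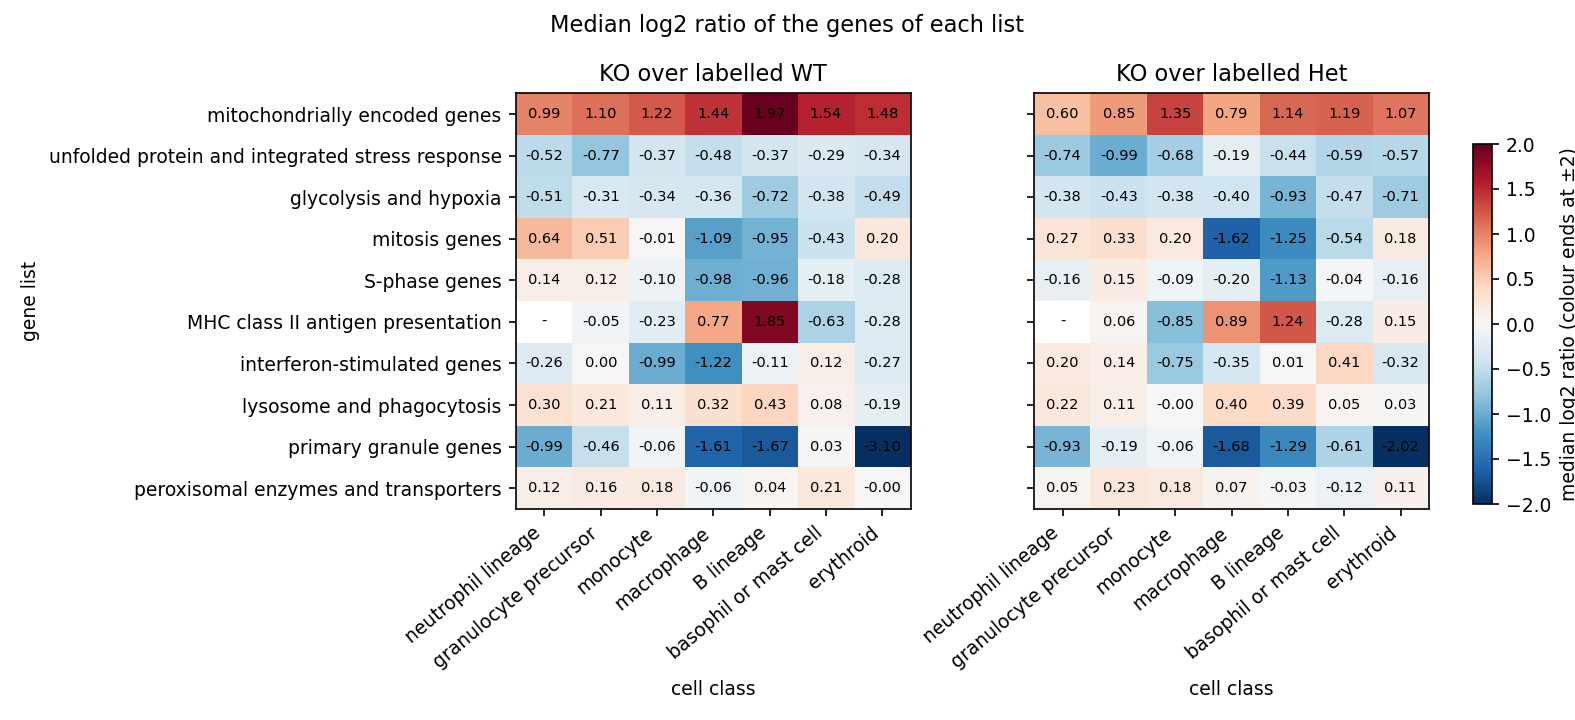
Median log2 ratio of KO over labelled WT and of KO over labelled Het as colour, for 10 gene lists in 7 cell classes, with the colour scale ending at 2 in each direction. Mitochondrially encoded genes are higher in KO in every class drawn (from 0.99 in the neutrophil lineage to 1.97 in the B lineage against labelled WT), whereas mitosis genes are higher in the neutrophil lineage (0.64) and lower in the B lineage (-0.95).

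Within neutrophil-lineage-like cells, cell division and mitochondrially encoded genes were higher in KO, and primary granule and stress-response genes were lower. Mitosis genes had medians of 0.64 against labelled WT and 0.27 against labelled Het (both percentile 100), with 27 of 30 members above both. Mki67, a marker of dividing cells, was at 315, 546 and 763 CPM, and Nuf2, which attaches chromosomes to the spindle, at 48.5, 75.2 and 122. Labelled Het over labelled WT was also high for this list, at 0.39 (percentile 100). S-phase genes stood apart in neither direction (0.14, percentile 87.4, and -0.16, percentile 6.84, with 0.14 for the second under TMM scaling). Primary granule genes had medians of -0.99 and -0.93 (both percentile 0), with the granule proteases and enzymes Elane at 1763, 2091 and 725 CPM and Mpo at 3952, 4098 and 1686. Granulocyte precursor-like cells, which make these granules, were 407 of 6038, 418 of 5008 and 218 of 5348 cells of the lineage, and within them the medians were -0.46 (percentile 2.02) and -0.19 (percentile 5.64). Secondary and tertiary granule genes had medians near 0 (-0.01 and -0.00), but members went both ways. Chil3 (5622, 9301 and 19937 CPM) and Lcn2 (11983, 16566 and 23166) were higher in KO. Camp (29846, 23210 and 16929) and Ltf (18906, 18007 and 12446) were lower.

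Single genes of the neutrophil lineage showed larger differences. Gstp3 was at 157, 133 and 2.77 CPM, and Myc, which drives growth and division, at 75.6, 136 and 16.6. Thbs1, a matrix protein released by myeloid cells and platelets, was at 1434, 1444 and 422 CPM, Nkg7, a protein of cytotoxic granules, at 116, 96.3 and 22.5, and Gabbr1, a receptor for the transmitter GABA, at 365, 194 and 59.2. Higher in KO were Glul, which makes glutamine (33.8, 58.6 and 200 CPM), F13a1, a clotting factor subunit (50.3, 65.9 and 231), Grap, an adaptor in receptor signalling (30.1, 26.6 and 106), Trp53inp1 (67.6, 54.8 and 205) and Scrg1, a small secreted protein (26.7, 41.8 and 117). Different clusters held these cells in each library, and Myc gave -1.20 in place of -2.19 against labelled WT and -2.35 in place of -3.04 against labelled Het, and F13a1 2.82 in place of 2.20, when predicted doublets were kept.

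Granulocyte precursor-like cells, most of them in cluster 10 with cells of all 3 libraries (347, 356 and 210), showed a similar pattern. The rest lay in sub-cluster 19.1, which held 60, 62 and only 8 cells. Myc, Srm and Cebpa are among its leading genes, so the mixture of cells in this class differed between libraries. Gstp3 was at 109, 90.0 and 1.32 CPM, and the mitochondrial genes mt-Atp6 and mt-Nd1 were at 206, 238 and 701 CPM and at 79.8, 134 and 385 CPM. Glul was at 43.9, 85.6 and 229 CPM. Haematopoietic transcription factors had medians of -0.81 (percentile 0) and -0.42 (percentile 0.06), with Cebpa, which directs granulocyte formation, at 335, 219 and 109 CPM. Unfolded protein and integrated stress response genes had medians of -0.77 and -0.99 (both percentile 0), with 21 of 24 members below both. Irf8, which steers precursors towards monocytes and dendritic cells, had a log2 ratio of KO over labelled WT of -4.28, Ccnd2 of -2.52, and Srm, an enzyme of spermidine synthesis, of -2.28. Keeping predicted doublets meant clustering and naming cells anew, so this class could then hold other cells. The median of all its genes against labelled WT moved from -0.11 to 0.18. In that setting the values for Irf8, Ccnd2 and Srm were -0.44, -0.43 and -0.41, and the value for Chil3 was 0.81 in place of 2.60. Against labelled Het they were -0.70, -0.52 and -0.63 in place of -3.19, -2.46 and -2.34, and Chil3 was 0.14 in place of 1.85. Ifitm6, a membrane protein of the interferon-induced family, lay above labelled Het by 1.36 and turned to -1.23 in that setting.

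Monocyte-like cells of KO showed more transcripts of Saa3, Trp53inp1, Chil3 and Mmp8 and fewer of Gvin1 and Dusp6. Saa3, an acute-phase protein, was at 16.3, 44.2 and 290 CPM, 17.7-fold above labelled WT (15.4 to 20.6) and 6.56-fold above labelled Het (6.10 to 7.08). Trp53inp1 was at 16.9, 15.2 and 192 CPM, Chil3 at 710, 1951 and 7991, the neutrophil collagenase Mmp8 at 316, 419 and 1737, and Wfdc21, a small secreted protein, at 113, 119 and 484. Neutrophil-lineage-like cells carried more of the last 3 in KO as well, with Mmp8 at 1198, 1014 and 2243 CPM, Chil3 at 5622, 9301 and 19937 and Wfdc21 at 1574, 1452 and 2375. In the B lineage Mmp8 was at 151, 82.0 and 158 and Wfdc21 at 146, 105 and 109, but Chil3 was higher in KO, at 447, 589 and 1088. In monocyte-like cells the neutrophil granule genes Ngp (2408, 2259 and 1230), Camp and Ltf were lower in KO. Another, Lcn2, was higher there, at 842, 1270 and 3075, so the source of neutrophil transcripts in these cells is uncertain. Gvin1, an interferon-inducible GTPase, was at 124, 124 and 11.3, Dusp6, a brake on ERK signalling, at 361, 369 and 52.4, Aif1, an actin-binding protein of macrophages, at 81.5, 75.3 and 16.1, and Bysl, needed to build ribosomes, at 96.4, 89.7 and 16.0.

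Gene lists in monocyte-like cells followed these genes. Interferon-stimulated genes had medians of -0.99 and -0.75 (both percentile 0), with 18 of 22 members below both, among them Irf7, the main driver of interferon production (77.0, 53.1 and 16.3 CPM), Zbp1, a nucleic acid sensor (49.2, 37.0 and 8.81), and Ifi27l2a (269, 259 and 63.7). Complement and scavenger receptor genes had medians of -0.66 (percentile 0.07) and -0.64 (percentile 0), with Axl, which binds dying cells, at 89.7, 82.0 and 32.2 CPM, while complement C3 was higher at 272, 295 and 523. Immediate early and heat shock genes had medians of -0.43 and -0.79. Mitochondrially encoded genes were higher, at 1.22 and 1.35 (both percentile 100). Most KO monocyte-like cells came from clusters 17 and 20, which few control cells shared, so cell state and library are hard to separate here.

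Macrophage-like cells (75, 77 and 116) had fewer transcripts of Cd209g and Cd209f and more of Gpnmb, Saa3, Mmp12 and Cxcl2 in KO. Cd209g and Cd209f, C-type lectins related to DC-SIGN, had 944, 967 and 3 UMIs and 755, 917 and 5 UMIs. Cd5l, a secreted inhibitor of macrophage death, was at 3562, 3928 and 246 CPM, and Dhx40, an RNA helicase, at 1492, 1023 and 40.1. Gpnmb, a lysosomal membrane protein of lipid-laden macrophages, had 3, 7 and 1269 UMIs, 144-fold above labelled WT (57.3 to 815) and 91.5-fold above labelled Het (47.4 to 244), or log2 ratios of 7.17 and 6.52 that were 5.98 and 5.84 with 5 counts added. Saa3 had 0, 0 and 314 UMIs, and the elastase Mmp12 had 0, 1 and 245. Cxcl2, which attracts neutrophils, had 3, 13 and 767 UMIs, and Igfbp1, a binder of insulin-like growth factors, had 1, 4 and 234. Igfbp1 is secreted by hepatocytes, and it was higher in KO outside this class too, with 6, 15 and 426 UMIs in the B lineage, so its source is uncertain. Apoe, which carries lipid out of macrophages, was at 15662, 15445 and 30629 CPM, the lysosomal protease Ctsl at 260, 447 and 1319, and lipoprotein lipase, Lpl, at 109, 91.3 and 29.6.

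Of the 116 KO macrophage-like cells, 91 lay in sub-cluster 28.1, which held no control cells. The other 25 KO cells shared sub-clusters with control cells and were also low in Cd209g (12.9 CPM against 1565 and 1177) and Cd5l (508 CPM against 3562 and 3928). They carried Gpnmb at 109 CPM and Saa3 at 96.4 CPM but no Mmp12 UMI, while Apoe (12291 CPM) and Ctsl (392 CPM) were not higher there than in both controls. The Kupffer cell receptor Clec4f was present in sub-cluster 28.1 at 2984 CPM, against 3951 and 3752 in control macrophage-like cells. Other macrophage markers were mixed there. Timd4 (231 CPM against 651 and 555), Adgre1 (317 against 613 and 583) and Marco were lower than in both controls. Cd163 was higher (1207 against 390 and 394), and Vsig4 lay between the controls. Interferon-stimulated genes had medians of -1.22 and -0.35 (both percentile 0), but labelled Het lay below labelled WT as well (-0.92, percentile 0). Among inflammatory cytokine genes directions were mixed, with Cxcl1 at 1, 2 and 52 UMIs and Ccl3 at 3, 7 and 111, but Ccl7 at 18, 143 and 0 and Il6 at 60, 34 and 2. The list had medians of -0.16 and -0.21.

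Macrophage-like cells of KO also had fewer transcripts of cell division. Mitosis genes had medians of -1.09 and -1.62, with 26 of 26 members below both, and S-phase genes had -0.98 and -0.20. Some neutrophil transcripts were lower in these KO cells too, with Ngp at 8669, 14154 and 4189 CPM and Camp at 5758, 7033 and 1211. Mmp8 and Chil3 lay between the controls, and whether both differences share a source was not tested. Lysosome genes were higher at 0.32 and 0.40, and hepatocyte secreted protein genes had medians of 0.71 (percentile 91.8) and 1.53 (percentile 99.8) over 4 members, the first of them 1.58 when members down to 1 CPM were taken. Hist1h2ap, a replication-dependent histone gene, had log2 ratios of -3.83 over labelled WT and -3.82 over labelled Het. These shrank to -0.63 and -0.17 when predicted doublets were kept and cells clustered anew.

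B-lineage-like cells of KO had fewer Vpreb1 transcripts and more light chain transcripts. The surrogate light chain gene Vpreb1 was at 154, 112 and 12.6 CPM, 12.2-fold below labelled WT and 8.83-fold below labelled Het. Light chain constant genes were higher, with Iglc1 at 108, 92.7 and 446 CPM and Iglc3 at 31.6, 29.7 and 146, as were Brwd1, a chromatin regulator of light chain recombination (17.6, 21.4 and 115), Egr1, an immediate early factor of receptor signalling (20.3, 29.9 and 136), and the variable segment Igkv8-30 (15.2, 15.2 and 129). Erg, a transcription factor of early B cells, was lower at 110, 104 and 19.6 CPM (log2 ratios of -2.48 and -2.41, or -1.75 and -1.69 with predicted doublets kept), as were Bcat1, which degrades branched amino acids (85.5, 125 and 15.6), and H1fx (151, 102 and 21.2). Ndufs5 (ENSMUSG00000028648), a nuclear-encoded subunit of complex I, was at 105, 113 and 2.82 CPM. Immunoglobulin segments resemble each other, so a probe may read more than 1 of them and these values are uncertain.

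Cell division lists were lower and MHC class II genes higher in the KO B lineage. Mitosis genes had medians of -0.95 and -1.25 (both percentile 0), with Plk1, a kinase of mitotic entry, at 204, 278 and 80.4 CPM. S-phase genes had -0.96 and -1.13, with 27 of 27 members below both, among them Lig1, which joins newly made DNA (424, 331 and 98.0), and Rrm2, which supplies nucleotides (1077, 895 and 315). MHC class II genes, which present antigen to T cells, had medians of 1.85 and 1.24 (both percentile 100), with 12 of 12 members above both. H2-Aa was at 17.6, 49.2 and 142 CPM, H2-Eb1 at 27.6, 59.1 and 189, and Cd74, the chaperone of these proteins, at 436, 563 and 1587. Glycolysis and hypoxia genes were lower at -0.72 and -0.93, cholesterol biosynthesis genes at -0.42 and -0.55, and sterol efflux and lipid handling genes were higher at 0.52 and 0.34. The B-cell progenitor cluster held 216, 147 and 5 cells and cluster 29 held 0, 3 and 312, so the mixture of stages within the lineage differed between libraries.

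Over all cells, unlike in the B lineage, MHC class II genes were lower in KO, with medians of -0.85 (percentile 0.03) and -0.95 (percentile 0), and H2-Aa was at 56.6, 115 and 18.6 CPM, H2-Ab1 at 45.8, 73.3 and 10.1 and Cd74 at 187, 253 and 88.1. Conventional dendritic cell type 1-like cells held 51.1%, 52.5% and 32.4% of all H2-Aa UMIs, and unnamed clusters held 42.5%, 37.6% and 31.5%. The B lineage held 3.71%, 4.03% and 24.6%. In the few dendritic-like cells themselves H2-Aa was at 9904, 13722 and 8363 CPM, H2-Ab1 at 7925, 8604 and 3065, H2-Eb1 at 8851, 12778 and 4970 and Cd74 at 20766, 22209 and 10855, with only 8 such cells in KO. Macrophage-like cells had higher medians in KO (0.77, percentile 97.8, and 0.89, percentile 99.2), although the first was 0.18 when only members above 50 CPM were taken, and Cd74 had 23, 16 and 310 UMIs there. Monocyte-like cells had medians of -0.23 (percentile 23.5) and -0.85 (percentile 0.035).

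Counted per cell after thinning to 3000 UMIs, a Cd74 UMI was found in 17.7% (15.6 to 19.8), 18.0% (15.9 to 20.3) and 28.8% (25.6 to 32.2) of B-lineage-like cells (unthinned 23.3%, 23.6% and 33.4%). For H2-Aa these shares were 1.87% (1.21 to 2.75), 3.31% (2.38 to 4.49) and 5.66% (4.12 to 7.55), and unthinned they were 2.92%, 4.72% and 7.37%. Neutrophil-lineage-like cells, which should lack H2-Aa, gave 0.305%, 0.429% and 0.0382%, a share read here as background, whose source was not tested. Among cells deep enough to be thinned, median depths were 5881, 7644 and 6061 UMIs in the B lineage and 8448, 16136 and 21348 in the neutrophil lineage, against 4066, 7068 and 5527 among all cells of the B lineage. Over all cells the thinned H2-Aa shares were 1.34%, 2.42% and 1.29%, and the thinned Cd74 shares were 6.60%, 6.49% and 4.53% (unthinned 12.2% in the library labelled WT and 7.28% in KO). The H2-Aa shares of KO and of the library labelled WT did not differ beyond counting error, unlike their CPM.

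The third comparison, labelled Het against labelled WT, gauged library differences without loss of both alleles, with the caution that Pex2 goes against these labels. Mt2, Car1, Car2, Hbb-bs and Mthfd2 were higher in the library labelled Het. All but Mthfd2 are among the leading genes of erythroid clusters, and erythroid-like cells were 1.31% and 3.28% of these libraries. Mt2, a metal-binding protein, was at 26.3 and 175 CPM, the carbonic anhydrases Car1 and Car2 at 20.5 and 89.3 and at 52.6 and 143, Hbb-bs, adult beta globin, at 54.5 and 180, and Mthfd2, a mitochondrial folate enzyme, at 55.2 and 161. Lower were Fam129c, a B-cell protein (184 and 85.1), Chst3, a sulphotransferase (119 and 57.0), mt-Nd6 (143 and 68.7), the gelatinase Mmp9 (1179 and 605) and Tspyl1, a nucleosome assembly factor (118 and 60.8). Over all cells, 0.817% of 8327 genes differed 2-fold or more for labelled Het over labelled WT. The share was 10.1% for KO over labelled WT and 7.09% for KO over labelled Het. The labelled Het over labelled WT share was also low in the neutrophil lineage (0.779%), the B lineage (0.778%) and monocyte-like cells (1.04%). It was higher in smaller classes, at 10.98% in macrophage-like, 6.55% in plasmacytoid dendritic-like, 4.97% in basophil or mast-like and 3.69% in erythroid-like cells. There KO over labelled WT gave 20.35%, 23.63%, 14.91% and 15.90%, and KO over labelled Het 18.26%, 19.23%, 6.99% and 6.48%.

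Several lists did not stand apart from random lists against both controls over all cells. MHC class I genes had medians of -0.31 (percentile 8.49) and -0.22 (percentile 18.5), oxidative phosphorylation genes 0.03 (77.6) and -0.05 (61.8), p53 targets and apoptosis genes -0.24 (30.7) and -0.20 (43.1), and cytokine receptors -0.11 (40.5) and 0.00 (79.0). Sterol efflux genes had -0.17 (45.6) and -0.12 (68.6), iron and heme genes -0.09 (61.9) and -0.16 (39.9), complement and scavenger receptors 0.03 (84.2) and 0.01 (93.4), and eicosanoid genes 0.16 (91.5) and -0.20 (25.4). Inflammatory cytokines had 0.00 (82.5) and -0.02 (89.5), immediate early and heat shock genes -0.18 (26.7) and -0.29 (4.23), interferon-stimulated genes -0.46 (8.46) and -0.23 (50.2), and mitosis genes 0.20 (99.0) and -0.00. Costimulation genes had 0.29 (97.9) and -0.10 (72.3), but the first was -0.47 when members down to 1 CPM were taken. Antioxidant genes had 0.28 (99.1) and 0.09 (93.7), S-phase genes -0.13 (31.3) and -0.31 (0.415), and secondary granule genes 0.15 and 0.10. TMM scaling turned the medians against labelled Het of MHC class I (0.12), interferon-stimulated (0.11), p53 (0.14), sterol efflux (0.22), iron and heme (0.18), eicosanoid (0.14), costimulation (0.24), immediate early (0.05) and S-phase genes (0.03). Primary granule genes were lower at -0.58 (0.62) and -0.60 (0.03). Ribosome and translation genes had -0.30 (10.4) and -0.61 (0.02), with labelled Het above labelled WT by 0.45 (percentile 100).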

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

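The test of a variant in the H2 region was chosen only after the result was seen, and thinning of Pex2 was added once the data were in view.

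Mitosis genes went in opposite directions between cell classes, which is why they are listed here. In KO against labelled WT their median log2 ratio was 0.64 in the neutrophil lineage, -0.95 in the B lineage, -1.09 in macrophage-like cells and -0.43 in basophil or mast-like cells. Mki67, which coats chromosomes in dividing cells, was at 315, 546 and 763 CPM in the neutrophil lineage and at 747, 1105 and 633 CPM in the B lineage. The difference between classes was not tested, since each genotype had 1 library, and no explanation of it was tested either. Labelled Het also lay above labelled WT in the neutrophil lineage, by 0.39.

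Pex2 was higher in the library labelled Het than in that labelled WT. After thinning, Pex2 was still 2.24-fold higher (2.02 to 2.47). CPM already scales for depth and thinning keeps each gene's expected share, so this result cannot weigh depth as the cause. Only 2 of 7236 autosomal genes lay 4-fold apart between these libraries in every class measured, which met the bound set in advance against a broad background difference. A like measure found only 3 genes apart in KO, so it is too strict to exclude a difference in genetic background. Exchanged labels stay open, because the test that needed genes near Pex2 found 0 of 0 usable genes, and a single variant under the Pex2 probe stays open too. A real difference in Pex2 expression between these libraries, which also differ in Y-linked expression, was not tested.

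MHC class II genes such as H2-Aa and Cd74 were lower over all cells of KO. A variant of the H2 region that weakens the probes stays open, since its test was chosen after the result was seen and cannot decide. The mixture of B-lineage stages also differed between libraries. In the B lineage 7 of 7 H2 members measured were higher in KO than in both other libraries, and in macrophage-like cells 4 of 4. The numbers so placed were 0 of 5 in monocyte-like, 0 of 4 in basophil or mast-like and 1 of 3 in erythroid-like cells, where 3, 3 and 2 members were below both. Cell composition stays open as well. With each class given the same weight in every library, the medians of the list relative to all genes were -0.42 and -0.43 over 10 members. These fell short of the bound of 0.5 set in advance and yet were not at 0. Conventional dendritic cell type 1-like cells and unnamed clusters, which held most H2-Aa UMIs, took smaller shares in KO. Within those dendritic-like cells, 8 of them in KO, H2-Aa and Cd74 were lower in KO as well. Loss of both Pex2 alleles also stays open, and cannot be told apart from other differences between these 3 libraries, whose number of animals is not known here.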

How the results depend on the processing

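Alternatives added after the data were seen were centred libraries, no sub-clustering, the earlier sub-clustering rule, smaller classes and Pex2 thinning. Of 242 class share ratios under an alternative, 233 stayed within the main interval, 8 moved and 1 reversed. Reversal of a share ratio was scored only where the main interval excluded 1. Those that stayed include values that could not move, such as those with all deposited barcodes kept or with other splitting rules for classes without split clusters. B-lineage-like ratios after clustering of thinned cells were 0.638 against labelled WT and 0.627 against labelled Het. Monocyte-like ratios were 2.13 and 1.85 at Leiden resolution 2, and 1.46 against labelled Het at resolution 0.5. Macrophage-like ratios were 2.54 and 2.10 with libraries centred. The basophil or mast-like ratios crossed 1 with each library clustered alone and were not scored as reversed. They went from 0.942 to 1.46 against labelled WT and from 0.789 to 1.115 against labelled Het. The neutrophil-lineage ratio against labelled WT reversed to 0.996 after clustering of thinned cells. For these shares the cause was not tested.

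Of 720 values of named genes, 471 stayed, 248 moved and 1 reversed. Ifitm6 in granulocyte precursor-like cells reversed to -1.23 against labelled Het with predicted doublets kept, and the cause was not tested. Of 1898 medians of gene lists, 1095 stayed, 800 moved and 3 reversed. A reversal was counted only where both main percentiles lay in the outer 2.5%, and 278 medians in all changed sign. Glycolysis genes over all cells reversed to 0.0107 against labelled Het under TMM factors, which lifted the median of all genes to 0.18. Eicosanoid genes in erythroid-like cells, with medians of -0.96 and -0.66, reversed to 0.029 and 0.086 at a minimum of 50 CPM, which leaves fewer members. Of 96 shares of cells with a UMI, 24 stayed and 72 moved, and reversal was not scored for them. Of 99 other values, 96 stayed and 3 moved.

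No paired analysis was possible because each genotype had 1 library. Keeping all deposited barcodes changed nothing, since the gene minimum removed 0. A class that formed no named cluster under a setting gave no value there. Rare classes rest on few cells, such as the 8 dendritic cell type 1-like cells of KO.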

Other observations

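The list of glucocorticoid-induced genes was chosen only after leading genes of KO had been seen, although its test was fixed before the list was measured. The minimum of 10 genes needed to decide the tests on genes apart in every class was set after only 3 had passed. The linkage test by chromosome was chosen only after the result was seen, since the planned count within 20 Mb of Pex2 was void, with 0.00663 genes expected there.

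Basophil or mast-like cells, which release histamine and proteases, lay in 1 cluster shared by the libraries (71, 71 and 57 cells). Slc28a2, a nucleoside transporter, was at 34.8, 276 and 2080 CPM and Gpr65, an acid-sensing receptor, at 8.19, 52.0 and 222 CPM, so both were graded from labelled WT through labelled Het to KO. Serpina3g, a protease inhibitor, was at 20.5, 21.5 and 116 CPM. The immediate early genes Fosb and Fos were lower in KO, at 483, 203 and 18.1 CPM and at 215, 118 and 23.8 CPM, and so was the nuclear lamina gene Lmna at 106, 69.9 and 14.8 CPM. Their list, immediate early and heat shock genes, had medians of -0.89 (percentile 0) and -0.21 (percentile 1.24). Fcnb, a ficolin made by neutrophils, was at 54.3, 216 and 4.92 CPM there, and the source of this transcript in these cells was not tested. Its log2 ratio of KO over labelled WT was -2.72 in place of -3.36 with 5 counts added.

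Erythroid-like cells of KO carried more Fam178b, a gene of red cell precursors (5.07, 26.2 and 196 CPM), Glcci1, a gene induced by glucocorticoids (20.9, 30.3 and 193), N4bp2l1 (9.02, 29.3 and 130) and Rap1gap, a brake on Rap1 signalling, whose log2 ratios were 3.21 and 1.89. They carried less Ndufs5 (69.9, 78.1 and 2.94 CPM), Mycn, a transcription factor of the MYC family (96.4, 60.3 and 8.29), and Igfbp4, a binder of insulin-like growth factors (190, 154 and 24.1). Tcrg-C1, a T-cell receptor constant gene, was at 30.4, 135 and 2.41 CPM.

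Plasmacytoid dendritic-like cells of KO numbered 23 and carried 0 UMIs of Ccnb2, a cyclin of mitosis, against 198 and 96 in the controls, and 0 of Hmmr against 95 and 56. Mitosis genes had medians of -4.09 and -3.60 there, with 30 of 30 members below both. These transcripts came mainly from sub-cluster 19.6, which held 24, 6 and 0 cells and also B-cell markers, with mitosis genes at 9326 and 10633 CPM in the controls. In sub-cluster 19.3, with 59, 34 and 23 cells, they were at 447, 500 and 225 CPM, and Ccnb2 had 15, 15 and 0 UMIs. Most of the difference thus lay in cells that KO lacked, and KO was lower in the shared cells too. Over the whole class neutrophil transcripts were also lower in KO, with Ngp at 4761, 4932 and 371 CPM and Camp at 3498, 2084 and 94.4. Whether both differences share a source was not tested. Klk1b22, a kallikrein protease, had 0, 13 and 108 UMIs, and Sytl3, a vesicle-docking protein, had 1, 5 and 71.

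Genes induced by glucocorticoids, the stress steroids, were higher in several classes of KO. In monocyte-like cells Fkbp5, a chaperone of the steroid receptor, was at 153, 325 and 478 CPM, Tsc22d3, which mediates the anti-inflammatory response, at 137, 221 and 377, and Per1, a clock gene, at 29.9, 138 and 261. The list had medians of 1.15 and 0.64 there, 1.84 and 1.49 in macrophage-like cells, 0.58 and 0.57 in the B lineage and 0.40 and 0.18 in the neutrophil lineage. Percentiles against the 2 controls were 100 and 100 in monocyte-like and macrophage-like cells, 99.4 and 99.8 in the B lineage and 98.4 and 97.1 in the neutrophil lineage. Both passed the bound set in advance in 3 of 4 classes, which is consistent with higher steroid exposure of the animal or animals behind the KO library as a hypothesis. Txnip, a member that limits glucose uptake, was lower in KO. Labelled Het lay above labelled WT too, at percentiles 93.0, 100, 97.2 and 99.9 in neutrophil, monocyte, B-lineage and macrophage classes, so an effect of genotype and another difference between the libraries both stay open.

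Some genes stood 4-fold or more apart in every class measured. Ndufs5 (chromosome 4, 123712710 to 123718202) was at 52.4, 51.9 and 2.14 CPM over all cells, Fosb at 29.7, 14.8 and 0.859, and Klk1b22 at 0, 1.83 and 17.0, so KO had 3 such genes. The library labelled Het had 1 of its own, Prss22, a serine protease (0.0931, 23.4 and 0.268 CPM), and that labelled WT had 0. A background variant may explain Ndufs5 or Klk1b22, but 1 such gene in a control against 3 in KO is too few to weigh it. A variant linked to the targeted locus was argued against for these genes, since 0 of the 3 lie on chromosome 3 with Pex2 and all lie on chromosomes 4 and 7.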
